A study of Mus musculus with 3 samples.

How the data were processed

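ChIP-seq was performed on 3 samples of mouse epididymal cells, 1 per condition: untagged PC1 cells at 33 °C, P17 cells with tagged AR at 33 °C and P17 cells at 37 °C. Per the labels' protocols, receptor complexes were taken up on magnetic beads carrying FLAG antibody under native conditions, and a gel-purified DNA fraction was sent for library preparation. Reads were processed with CASAVA 1.8 and peaks were called with MACS on genome build mm9, per the submitters' processing notes. The MACS version, its settings, the handling of duplicate tags and any control library used in peak calling are not given in the sources used here. This matters for every comparison of the lists, because a list called with other settings or without a control differs from the others for that reason alone.

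Each deposited peak table gives 1 library's peaks with start, end, width, summit offset, a count of tags per peak and a p-value per peak, per the file headers. The tag count is an unnormalized whole number for that library alone, and the sources used here give no count for regions that were not called in a library. The deposited p-value is the authors' peak caller's own measure and no p-value exceeds 1e-05 in any table. It was used here as a score of 10 times −log10 p, to describe, rank and filter peaks of each list and to set peaks of different lists side by side in score classes. Because depth and caller settings are unknown, equal scores in different lists need not mean equal enrichment. Both 33 °C tables write p-values with a decimal comma, which was read as a decimal point. The 37 °C table uses a decimal point and another spelling of that column's name, and whether it came from a separate run of the peak caller is not given in the sources used here. No fold enrichment or false discovery rate was used, since the tables hold none. A further track of the 37 °C sample is deposited as log2 values; it lists the same 3622 regions, and in all 3622 the value equalled log2 of that score within 5.1e-05, so it adds no measurement. No table has peaks that overlap each other. Positions are given as in the tables, counted from 1, in mm9.

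Peaks of different lists were called overlapping at 1 bp or more. Tagged-specific peaks were those meeting no untagged peak. Overlap by chance was described by 1000 circular shifts, in which all peaks of a chromosome were moved by 1 random distance, with the highest peak end in any list taken as the chromosome's length. Shares carry 95% Wilson intervals, differences of shares Newcombe intervals and single tag counts exact Poisson intervals. Tag counts were compared between libraries at regions where exactly 1 peak met exactly 1 peak. Exceptions were the counts of named peaks, the test of depth at untagged peaks of 500 or more tags, and totals per list or stretch. Peak edges were set separately in each library. Overlap code was tested on simulated data: for the comparison of the 33 °C lists, the known overlap of 3 simulated lists of 4524 peaks was recovered within 0.2 percentage points, and 12 of 12 overlap counts on the deposited lists equalled those of bedtools 2.31.1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

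The design, the alternatives and the rule for naming peaks were fixed before the data were examined. The comparison of 37 °C recovery between tagged-specific and untagged-only regions, with its score classes, was not part of that design. In each of 4 classes (tagged-specific at 33 °C with no peak at 37 °C, the converse, tagged-specific at both temperatures, and untagged) the 8 peaks with the highest score were named, ties going to the higher tag count. For the class at both temperatures the lower of the 2 scores ranked a region. Crowded blocks, defined after the counts were seen, were runs of adjacent 1-Mb bins in which each tagged list held at least 10 peaks and at least 2 times as many as the untagged list. The alternatives were a score of at least 100, removal of chromosome Y (the tables list no mitochondrial or unplaced peaks), overlap of at least 50% of both peaks, summits within 200 bp, lists of equal length, untagged peaks widened by 1 kb, and tagged lists with no untagged peaks taken away.

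No mm9 annotation or sequence was used here, and the reference at hand names genes on GRCm38, another build, so peaks were not assigned to genes. The planned comparisons with 8 gene lists, with the androgen response element and with promoters and repeats were therefore not run. The GRCm38 table served only for the number of protein-coding genes per chromosome.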

Results

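The androgen receptor (AR), the nuclear receptor through which testosterone acts on gene transcription, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in cells of the mouse proximal caput epididymis, the first part of the duct in which sperm mature. PC1 is the parental cell line. P17 is a line made from PC1 that expresses a tagged mouse AR, so that an antibody against the FLAG epitope can pull the receptor down together with the DNA it occupies. The design compared PC1 at 33 °C, which carries no tag and served as the negative control, P17 at 33 °C, when the cells proliferate, and P17 at 37 °C, when they do not, with 1 library of each. With 1 library per condition no difference has a replicate check, and no p-value between conditions is given. The shares and intervals below describe these 3 libraries, and the intervals cover counting error only.

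The authors' peak lists held 5259 regions in the untagged library, 4524 in the tagged library at 33 °C and 3622 in the tagged library at 37 °C. Peaks of both 33 °C lists had nearly the same median width, 708 bp without the tag and 700 bp with it, and median tag counts of 37 and 40 per peak. The 37 °C peaks were wider (median 1153 bp) and held more tags (median 107 per peak). In total 310095, 288641 and 668377 tags lay inside the called peaks of the untagged, 33 °C tagged and 37 °C tagged libraries. The number of tags outside peaks, and so the full sequencing depth, is not given in the sources used here. Each peak's significance is given below as a score, 10 times the −log10 of the authors' peak p-value, which was 50 or more in every list. The median score was 108 without the tag, 116 with the tag at 33 °C and 73.8 with the tag at 37 °C.

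The comparison of tagged with untagged cells at 33 °C asks which regions depend on the tagged receptor in proliferating cells. Most regions recovered from the tagged cells were also recovered from cells with no tag. Of the 4524 tagged peaks, 3368 overlapped an untagged peak by at least 1 bp (74.4%, 95% Wilson interval 73.2 to 75.7). When the peaks were moved around their chromosomes by random distances, the highest overlap in 1000 such shifts was 0.774%. Among the 2540 tagged peaks with a score of at least 100 the overlapping share was 94.7% (93.7 to 95.5). Seen from the other side, 3365 of the 5259 untagged peaks (64.0%, 62.7 to 65.3) overlapped a tagged peak at 33 °C.

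All 8 of the highest-scoring untagged peaks were called in the tagged cells at 33 °C, with similar tag counts. The peak at chromosome 9, 35112509 to 35113537 (mm9), held 574 tags without the tag (95% Poisson interval 528 to 623) and 550 with it. The region with the most tags, chromosome 1, 24618119 to 24623077, held 6562 tags without the tag and 5713 with it. On chromosome 2, the regions 98506008 to 98507620, 22442753 to 22445731 and 81482783 to 81483133 held 1826, 1193 and 233 tags without the tag, against 1794, 1025 and 200 with it. The remaining 3 lay on chromosome 15 (74915512 to 74917851; 951 and 782 tags), chromosome 7 (104291533 to 104291887; 222 and 196 tags) and chromosome 8 (68354646 to 68355111; 298 and 262 tags).

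Tag counts at regions that both 33 °C lists shared followed each other closely. Over 3330 regions where 1 peak of each list met 1 peak of the other, the median log2 ratio of tagged to untagged counts was −0.09 (SD over regions 0.47). Pearson's r of the log counts was 0.882 and Spearman's rho 0.827, both across regions of a single pair of libraries, which are not independent replicates. Relative to the median, 77 regions held at least 2 times more tags in the tagged library and 24 at least 2 times fewer. Of the 77 higher regions 29 lay on chromosome X or Y, against 1 of the 24 lower ones.

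**Figure D1:**
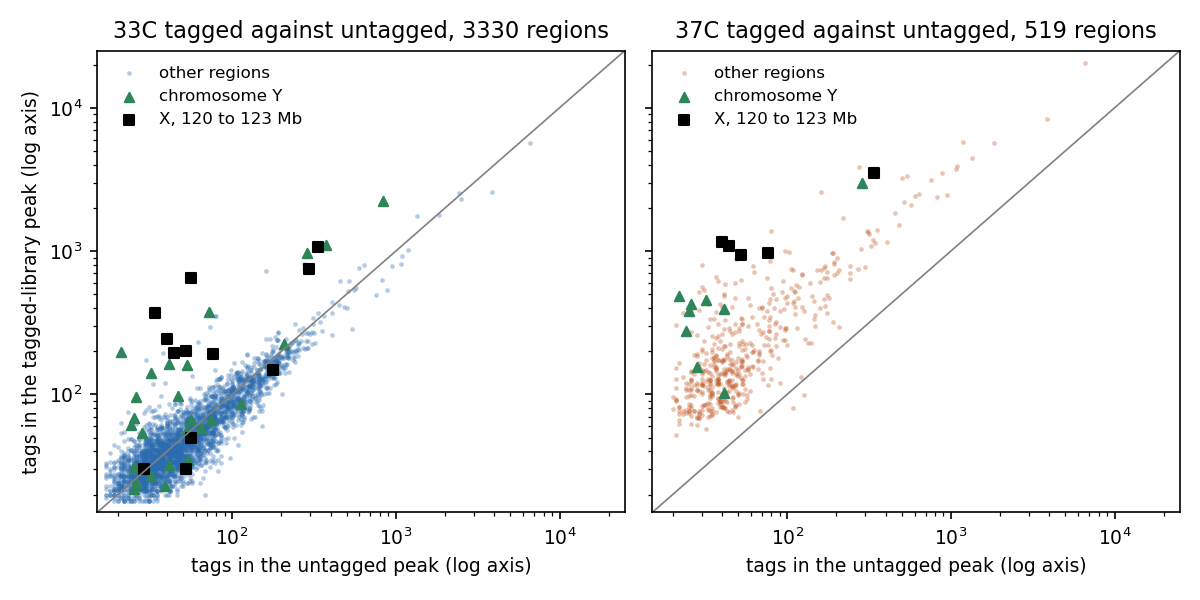
Tags per peak (log axes) at regions that a tagged list and the untagged list both hold, 1 point per region, for the tagged library at 33 °C (left, 3330 regions) and at 37 °C (right, 519 regions); the grey line marks equal counts. At 33 °C most points lie along the line, with a median log2 ratio of −0.09, while regions of chromosome Y and of X between 120 and 123 Mb include many points above it; at 37 °C the median log2 ratio was 1.83.

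Tagged-specific peaks at 33 °C, those meeting no untagged peak, numbered 1156, and untagged-only peaks, those meeting no tagged peak at 33 °C, numbered 1894. The median score was 62.3 for the tagged-specific peaks (highest 328) and 64.5 for the untagged-only peaks (highest 350.2). A score of at least 100 was reached by 135 of the tagged-specific peaks (11.7%) and by 263 of the untagged-only peaks (13.9%).

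At 852 of the tagged-specific 33 °C peaks no peak was called at 37 °C either. The strongest of these, chromosome X 89785993 to 89786258, was 266 bp wide and held 34 tags (95% Poisson interval 23.5 to 47.5; score 328). Next came chromosome 14, 60949463 to 60949689, with 23 tags (14.6 to 34.5; score 223). Chromosome 2 held 2 of the first 8, at 66218794 to 66219287 (41 tags) and 140147402 to 140148285 (52 tags). The others were on chromosome 18 at 58444640 to 58445285 (47 tags), chromosome 16 at 53593642 to 53594061 (37 tags), chromosome 14 at 92360491 to 92361418 (54 tags) and chromosome 7 at 100361697 to 100362052 (32 tags).

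Tagged cells at 37 °C were set against the same untagged library, which had been kept at 33 °C, so that tag and temperature differ together in this comparison. The 37 °C table also differs from both 33 °C tables in number format, and it is not known whether its peaks were called in the same way. Here most regions were absent from the untagged list. Only 530 of the 3622 peaks (14.6%, 13.5 to 15.8) overlapped an untagged peak, which left 3092 tagged-specific peaks, and the share was 59.8 percentage points below that at 33 °C (58.1 to 61.5). Among the 1100 peaks at 37 °C with a score of at least 100 the overlapping share was 27.9% (25.3 to 30.6). It was 8.95% when the 3 lists were made equally long by score. Conversely, most regions of the 33 °C untagged list were not called. Of the 5259 untagged peaks, 541 (10.3%, 9.49 to 11.1) met a 37 °C peak, or 6.69% with all lists restricted to scores of at least 100. Of the 607 untagged peaks with at least 100 tags, 103 met one (16.97%), against 589 (97.0%) at 33 °C.

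Untagged regions with the highest tag counts were mostly common to all 3 libraries. Of the 23 untagged peaks with at least 500 tags, 23 met a peak at 33 °C and 21 at 37 °C. Among the 8 named untagged peaks 5 were called at 37 °C, with 2112 tags at the chromosome 9 region, 20578 at the chromosome 1 region, 5715 at chromosome 2 from 98506008, 5812 at chromosome 2 from 22442753 and 2452 at the chromosome 15 region. No 37 °C peak was called at chromosome 2 from 81482783, chromosome 7 from 104291533 or chromosome 8 from 68354646. At the 519 regions called in both lists, which leave out those with too few tags to be called at 37 °C, that library held 2.48 times as many tags per bp as the untagged library (median log2 ratio 1.31, SD over regions 0.50). The lowest tag count of any peak was 39 in the 37 °C list, against 17 and 18 in the untagged and tagged lists at 33 °C. A region with fewer tags than 39 at 37 °C counts as not called there and enters no comparison of tag counts.

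**Figure D2:**
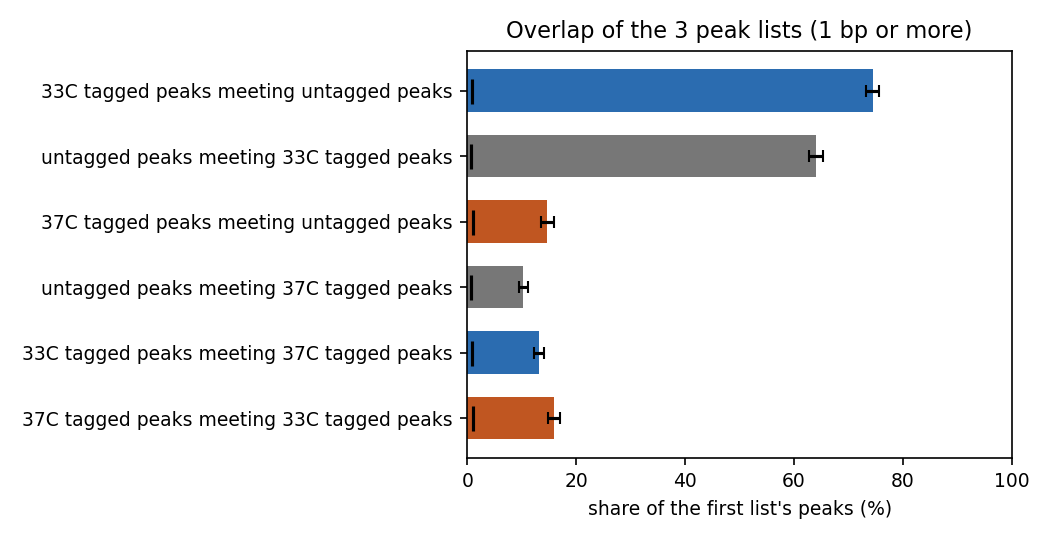
Share of each list's peaks (bars, in percent) that overlapped a peak of another list by at least 1 bp, with 95% Wilson intervals as error bars and the highest of 1000 random shifts as black ticks. The tagged and untagged lists at 33 °C shared 74.4% and 64.0% of their peaks, and each comparison with the 37 °C list gave between 10.3% and 15.9%.

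The 3092 tagged-specific peaks at 37 °C had a median score of 70.6, and 793 of them (25.6%) reached 100. At 2797 of them no peak was called in the tagged cells at 33 °C. First among these stood chromosome X, 166526629 to 166527668, with 1462 tags (95% Poisson interval 1388 to 1539) and a score of 3100, which corresponds to the smallest p-value in that table (1e-310) and is shared by 22 of its peaks. The peak at chromosome 14, 86598261 to 86599461, held 639 tags (590.4 to 691; score 2965). A second peak on chromosome 14, at 91310659 to 91311408, held 281 tags. Peaks on chromosome Y (2651675 to 2652827), chromosome 9 (123781699 to 123782494) and chromosome 1 (195053453 to 195054667) held 369, 297 and 430 tags. The last 2 of the 8 lay on chromosome 2 at 69193047 to 69194247, with 413 tags, and on chromosome 16 at 93788878 to 93790132, with 497 tags.

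The comparison of proliferating with non-proliferating tagged cells, which the series was designed for, was made on the tagged-specific peaks. Of the tagged-specific regions, 298 of the 1156 peaks from 33 °C met a 37 °C tagged-specific peak (25.8%, 23.3 to 28.4), and 294 of the 3092 peaks from 37 °C met one from 33 °C (9.51%, 8.52 to 10.6). The highest shares in 1000 random shifts were 1.56% and 0.453%. For the same peaks, counting them as shared only when summits lay within 200 bp gave 15.7% and 5.85%, and overlap of at least 50% of both peaks gave 19.98% and 7.47%. Without taking untagged peaks away the shares were 13.1% from the 33 °C side and 15.9% from the 37 °C side. The order of the sides turned over with list length, since nearly equal numbers of overlapping peaks (593 and 575) were divided by 4524 and 3622. Of the tagged-specific peaks with a score of at least 100, 51 of 135 from 33 °C (37.8%, 30.04 to 46.2) and 152 of 793 from 37 °C (19.2%, 16.6 to 22.1) were shared. When all 3 lists were first restricted to such scores, which makes peaks meeting a weaker untagged peak count as tagged-specific, the shares were 17.02% of 429 and 7.94% of 919.

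Recovery at 37 °C was more frequent for regions specific to the tagged cells at 33 °C than for regions found only without the tag. Both shares exceeded that of 33 °C tagged peaks that also met an untagged peak, 289 of 3368 (8.58%). Over all scores, presence in the tagged cells at 33 °C thus did not by itself go with higher recovery. Scores differed, with a median of 160 for these shared peaks and 64.5 for untagged-only peaks. By score class, shared peaks were recovered more often from 50 to 60 (12.7% against 10.2% of untagged-only peaks) and from 200 up (8.18% against 0 of 21). They were recovered less often from 60 to 80 (11.1% against 17.5%), 80 to 120 (7.89% against 14.9%) and 120 to 200 (7.26% against 9.17%). A 37 °C peak was present at 304 of 1156 tagged-specific regions (26.3%) and at 255 of 1894 untagged-only regions (13.5%), a difference of 12.8 percentage points (95% Newcombe interval 9.90 to 15.8). Without chromosomes X and Y the difference was 8.35 points (5.36 to 11.4). Of these regions with a score of at least 100, 54 of 135 tagged-specific (40.0%) and 27 of 263 untagged-only ones (10.3%) met a 37 °C peak. When all 3 lists were first restricted to such scores the shares were 17.2% and 5.50%. For all 1156 tagged-specific and 1894 untagged-only regions, summits within 200 bp gave 15.7% and 7.76%, and overlap of at least 50% of both peaks 20.1% and 11.4%. Within classes of each list's own score the tagged-specific share was higher each time, at 21.1% against 10.2% for scores from 50 to 60 and at 36.4% against 9.17% for scores from 120 to 200. Above a score of 200 there were 12 tagged-specific regions, of which 10 were found at 37 °C, and 21 untagged-only regions, of which none was found (upper Wilson limit 15.5%). The 8 strongest regions of both temperatures, given next, are among the 10, and 6 of the 8 lay on X or Y. The score classes were not recomputed without these chromosomes. Tagged-specific regions and the 37 °C list both come from P17, untagged-only regions from PC1. Any other difference between the lines could give the same excess and was not tested.

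Sex-chromosome regions led the set present in tagged cells at both temperatures and absent from the untagged list. Of the 8 strongest by the lower of their 2 scores, 6 lay on X or Y. On chromosome Y these were 1655276 to 1656843 (100 tags at 33 °C and 192 at 37 °C), 1742739 to 1743754 (75 and 166), 1633210 to 1636379 (209 and 862) and 1713819 to 1715558 (101 and 409). On chromosome X they were 121214119 to 121217545 (346 and 1024 tags) and 53205968 to 53207652 (119 and 312 tags). The 2 autosomal regions were chromosome 2, 98175464 to 98177746 (158 and 508 tags), and chromosome 3, 28779461 to 28782338 (211 and 620 tags). Positions are those of the 33 °C peaks, and each 37 °C count belongs to a 37 °C peak with its own edges. Higher counts at 37 °C were general and not particular to these regions. At 558 regions where 1 peak of each tagged list met 1 peak of the other, the median log2 ratio of 37 °C to 33 °C tags was 1.83 (1.28 per bp). With the criterion of summits within 200 bp, 5 of the 8 regions stayed in the class of both temperatures.

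The block of chromosome X between 120 and 123 Mb, which was singled out after the values were seen, held 16 untagged peaks, 63 tagged peaks at 33 °C and 100 at 37 °C. With scores of at least 100 these counts were 8, 18 and 53. The block contained 37 of the 294 regions present at both temperatures (12.6%). Outside it, the fullest 1-Mb bin of X held 16 peaks at 37 °C and 12 tagged peaks at 33 °C, both between 53 and 54 Mb, and 8 peaks without the tag. Chromosome X as a whole was not crowded at 37 °C. It held 178 peaks there (4.91% of the list), against 403 untagged peaks (7.66%) and 426 tagged peaks at 33 °C (9.42%).

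**Figure D3:**
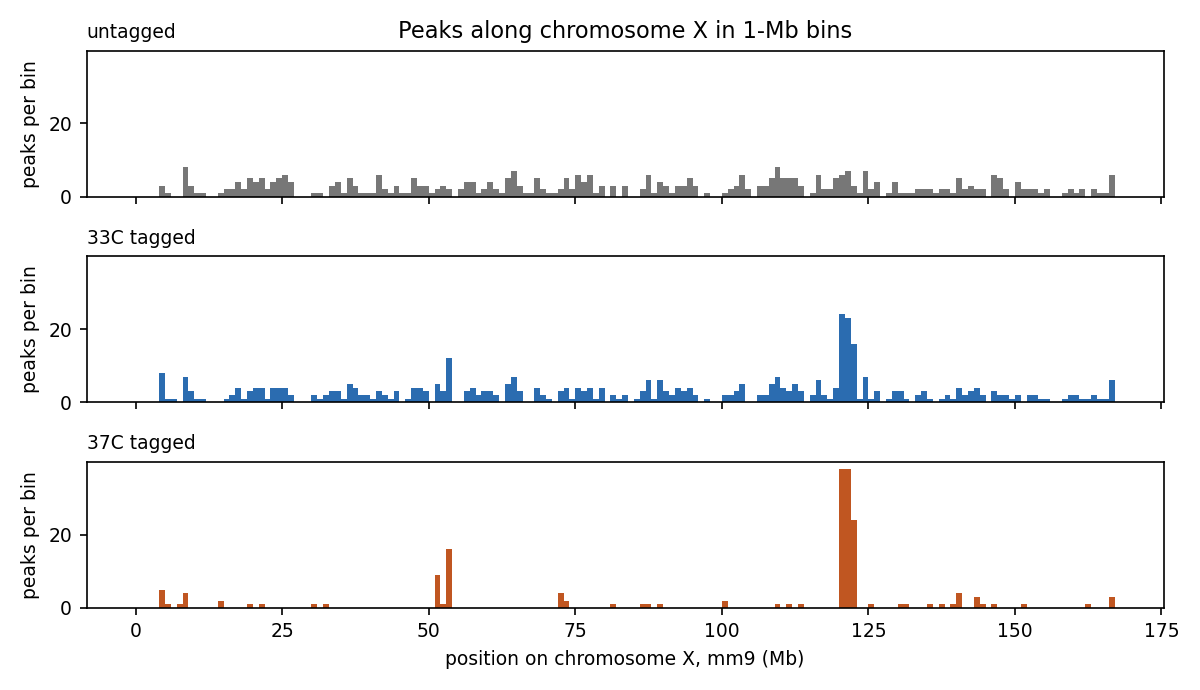
Number of peaks per 1-Mb bin along chromosome X (mm9) in each of the 3 peak lists, on a common axis. The block from 120 to 123 Mb holds 63 and 100 peaks in the tagged lists at 33 °C and 37 °C and 16 in the untagged list.

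Peaks at 37 °C were spread unevenly over the chromosomes. Chromosome 5 carried 511, chromosome 8 carried 415 and chromosome 10 carried 369, together 35.8% of the list (34.2 to 37.3). The same 3 chromosomes, chosen after the counts were seen, held 17.8% of untagged peaks (16.8 to 18.9) and 17.7% of tagged peaks at 33 °C (16.6 to 18.8). The excess at 37 °C was larger among weaker peaks: chromosomes 5, 8 and 10 held 40.5% of 37 °C peaks with scores from 50 to 60 (37.5 to 43.6) but 17.6% of those with scores of 400 or more (13.4 to 22.8). For untagged peaks the shares in these score classes were 25.4% (22.7 to 28.3) and 12.2% (10.2 to 14.6).

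**Figure D4:**
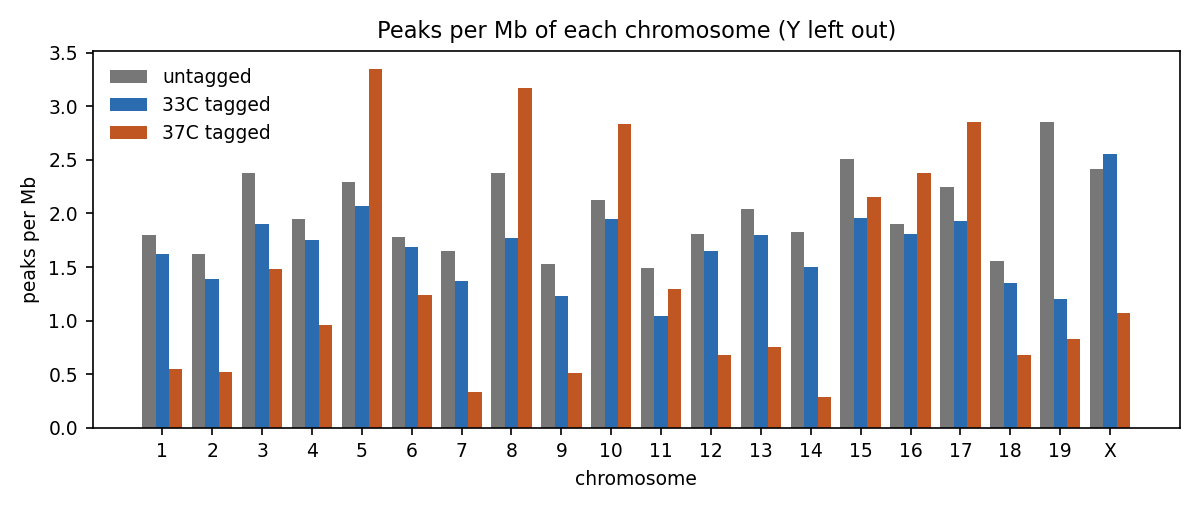
Peaks per Mb of each chromosome (Y left out) in the untagged, 33 °C tagged and 37 °C tagged lists, with the highest peak end of any list taken as the chromosome's length. The 37 °C list has 3.35 peaks per Mb on chromosome 5, 3.17 on chromosome 8, 2.86 on chromosome 17 and 2.84 on chromosome 10.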

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

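The 33 °C tagged list shared more of its peaks with the untagged list than the 37 °C list did under each alternative run, with 67.5% to 83.1% against 8.95% to 16.5%, and with 94.7% against 27.9% for tagged peaks of score 100 or more set against the whole untagged list. Alternatives of score, overlap or list length applied to all lists, and so also changed which peaks counted as tagged-specific. Of 44 recomputed values for the numbers of peaks and the shares overlapping untagged peaks or common to both temperatures, 20 stayed within the interval of the original share or within 1.5 times the original count and 24 did not. A score of at least 100 left 2782 untagged, 2540 tagged 33 °C and 1100 tagged 37 °C peaks, with 429 and 919 tagged-specific peaks; shares overlapping untagged peaks were then 83.1% and 16.5%, and shares common to both temperatures 17.02% from the 33 °C side and 7.94% from the 37 °C side. Overlap of at least 50% of both peaks gave 67.5% and 11.8% for the overlap with untagged peaks and 16.8% and 7.76% for peaks common to both temperatures. Summits within 200 bp gave 72.5%, 9.99%, 15.7% and 5.98% for the same values. Lists of equal length gave 76.3% and 8.95% for the overlap with untagged peaks and 6.49% for 37 °C peaks found at 33 °C. Without taking untagged peaks away the shares common to both temperatures were 13.1% and 15.9%. The larger share was then on the 37 °C side, because that list was then the shorter. Without chromosomes X and Y, an alternative chosen after seeing the data, the shares were 22.0% and 7.62%. Removal of chromosome Y and widening of untagged peaks by 1 kb moved none of the 44 beyond those limits. A threshold on false discovery rate could not be applied, since the tables hold none, and alternatives that need an mm9 annotation or sequence were not run. Every setting reuses the same 3 libraries, so stability here says nothing of variation between cultures, and absence of a peak cannot be told from a count just under the caller's threshold.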

Other observations

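The tests on the recovery of untagged peaks from 37 °C by depth and by cell identity, on the whole X chromosome and on chromosomes 5, 8 and 10 (low-scoring untagged peaks and tags per region) were chosen after the patterns had been seen; the tests of widened peaks, of copies of the X block and of gene density were stated before their results were computed.

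Other stretches of the genome held more peaks in both tagged lists than in the untagged list. Chromosome 4 between 146 and 147 Mb held 6 untagged peaks, 16 tagged peaks at 33 °C and 15 at 37 °C, and 9 regions there were tagged-specific at both temperatures. Chromosome X between 53 and 54 Mb held 2, 12 and 16 peaks in the same order. Chromosome Y as a whole held 32, 48 and 53 peaks, short of 2 times the untagged count, with 2884, 8553 and 15354 tags. At 26 regions of Y that both 33 °C lists hold, the log2 ratio of tagged to untagged tags was 0.72 above the autosomal median (SE 0.50). Of these, 17 lay above that median. Whether P17 carries more copies of Y sequences than PC1 was not tested. The stretches of chromosomes 4 and X were picked because they were crowded, and chromosome Y because it held several of the highest-scoring regions of both temperatures.

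Few untagged peaks were recovered at 37 °C: 10.3%, against 64.0% at 33 °C. Shallower sequencing that lowers all regions alike is argued against by the 23 untagged peaks with 500 or more tags. This holds only if duplicate tags were handled alike in all libraries, which is not known. At 37 °C, 21 of the 23 held more tags per bp (17 of them where 1 peak met 1 peak). The median log2 ratio was 1.68 (95% bootstrap interval 1.39 to 1.81) with the 2 that were not called ranked lowest. Of the 122 with 200 or more tags only 45 were called (44 with more tags per bp), so a loss limited to regions of fewer tags stays open. Shifted peak edges are argued against too, since widening the 37 °C peaks by 1 kb on each side raised recovery only to 10.4% (9.62 to 11.3). A 33 °C tagged library taken by mistake from untagged cells is argued against less firmly: it would not share the crowding that the 37 °C list shows on X at 120 to 123 Mb, yet in this block, which the 37 °C list alone also picks as its fullest, it held 3.94 times as many peaks as the untagged list (95% interval 2.25 to 7.30), though with scores of at least 100 the 18 and 8 peaks gave an interval of 0.931 to 5.98. Both intervals count the peaks of the block as independent, and they are too narrow if those peaks share repeated sequence, which was not tested. What stays open is a difference in peak calling, in the purification or in fragment size between the 37 °C library and the others. A true effect of temperature or growth arrest stays open too. With 1 library each, and no untagged library at 37 °C among those used here, these were not tested.

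Tagged peaks crowded into X at 120 to 123 Mb in both P17 libraries. A gain or loss of the whole X chromosome is argued against, since at 288 regions elsewhere on X the log2 ratio of 33 °C tagged to untagged tags differed from the autosomal median by only 0.024 (SE 0.038). A candidate explanation is that P17 carries more DNA copies of sequences in this block than PC1: at 12 regions of the block that the untagged list also holds, tag counts in the tagged library were higher by 1.60 on the log2 scale relative to autosomes (SE 0.57), or by 0.91 per bp, and 9 of the 12 lay above the autosomal median. The 12 ranged from −0.70 to 3.64, so a single gain of the whole block would not give all of them. Occupancy by the tagged receptor across the block would raise the same counts and stays open, as does multiple mapping of repeated sequence, which was not tested.

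By number, the 37 °C peaks were crowded on chromosomes 5, 8 and 10. Per Mb, chromosome 17 held 2.86 of them, against 2.84 on chromosome 10, and chromosome 17 counts among the other autosomes below. Gene density is argued against, since over the 19 autosomes the tagged-specific peaks per Mb had a Spearman rho of 0.016 with protein-coding genes per Mb (−0.10 to 0.17 when 1 chromosome was left out). Whether regions there gained tags at 37 °C stays open: the log2 ratio of tags per bp to the untagged library differed from that on other autosomes by −0.0072 (SE 0.039), but only the 10.6% of autosomal untagged peaks called at 37 °C bear on it. The density of 37 °C tagged-specific peaks did follow that of low-scoring untagged peaks (score under 60), with a rho of 0.73 (0.69 to 0.86 when 1 chromosome was left out), against −0.23 for untagged peaks of score 200 or more. This is consistent with part of the weak 37 °C peaks being background that tagged and untagged lines share, and a chromosome gain common to both lines could not be examined from peak lists.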
